A study of Mus musculus with 6 samples.

How the data were processed

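Ly6D-negative common lymphoid progenitors from 3 control (OcnCre-negative) and 3 mutant (OcnCre-positive) samples were profiled, 1 array each; every mouse carried iDTR and received toxin. Samples were grouped by the genotype in their source labels, and the replicate numbers come from the sample titles. Per the labels' protocols, cells were sorted by flow cytometry on low lineage markers, Kit, Sca, CD127, and absence of Thy1.2 and Ly6D, RNA was extracted with Trizol, amplified as cDNA by the NuGEN Ovation process and labelled with biotin. The deposited values are log2 probe set intensities made with RMA, per the submitters' processing notes; its version, the annotation and the genome build are not given in the sources used here, so no coordinates are printed. RMA corrects the background, makes the arrays' distributions alike and summarises probes into 1 value per probe set. It leaves no detection call, so a low value cannot be separated from background.

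The table held 41345 probe sets. Names came from a platform annotation table: 23521 probe sets had 1 gene symbol, 1814 had several genes and 16010 had no gene listed, 190 of these being control probe sets. Only probe sets with 1 symbol were named. Of them 23328 matched a gene identifier in a RefSeq table of assembly GRCm38.p6, and 0 had another symbol there. Each of 22180 genes was represented by its probe set with the highest mean over the 6 arrays. The lowest 40% of genes by that mean (under 4.84) were not tested, which left 13308. Ly6a and Tcf7 were not analysed here because no probe set carried only their name. Some other list members, among them Rag1, were untested for the same reason.

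Mutant was compared with control in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjustment, threshold 0.05). Gene lists were tested with camera at a preset inter-gene correlation of 0.01, over 28 lists with at least 3 tested members, and a sex-linked list was kept as a check of the samples. Camera asks whether a list moved relative to the other genes. It was repeated with an estimated correlation, under which 0 of the 9 passing lists passed, and with fry, which tests whether a list's genes move on balance in 1 direction. A list's score on an array is the median over its tested members of the log2 value minus the control mean. Errors of differences are limma's standard errors. Figures were drawn with matplotlib 3.10.9. Data were simulated for the 13308 genes for mutant against control. On them the test recovered 88% of genes changed by 1 on the log2 scale and 99% of those changed by 2, with 12 unchanged genes called. The simulated noise was normal and independent between genes and arrays, with no outlying array and no trend with brightness. These shares are therefore not the power of the test on the real arrays, where 37 genes differed by over 1 and 0 passed. With only the S phase list lowered by 0.3, 1 list was called, which was the S phase list. Because the simulated genes did not move together, this run cannot show how often camera calls lists whose genes do.

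The samples, the test, the lists, the named genes and most alternatives were chosen before the data were examined. The named genes were, per direction, up to 12 genes past the threshold whose groups did not overlap, filled to 8 with the lowest unadjusted p where fewer passed. Predicted genes were passed over in that filling, 3 among the higher and 1 among the lower. For each list, members past the threshold over all genes or over the list alone were named, or otherwise the 3 members with the lowest p. Sort, Notch, homing and lineage genes, Bglap and Hbegf were always named. The alternatives were no filter on dim genes, a stricter one (60%), the mean of all probe sets of a gene, every probe set alone, a trended and robust variance prior, array weights, an unmoderated test, repeated quantile normalization, centring on array medians, the replicate number as a block, other thresholds, estimated correlation, fry, lists without shared members, no sex-linked genes, and leaving out each array in turn. Cyclic loess, Y-linked expression as a block, Xist as a covariate on the log2 or linear scale and the 4 arrays with high Y-linked expression were added after seeing the data.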

Results

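Ly6D-negative common lymphoid progenitors are early bone marrow cells that can still give rise to T, B and natural killer cells. They were sorted from OcnCre;iDTR mice, in which Cre recombinase driven by the osteocalcin promoter switches on a receptor for diphtheria toxin, so that toxin kills osteocalcin-expressing bone cells. Toxin was given every day for 4 weeks both to mutant mice, which carried Cre, and to control mice, which did not. The comparison asks how the loss of osteocalcin-expressing cells alters the transcripts of these progenitors. RNA of 3 control and 3 mutant samples was measured on Affymetrix arrays, 1 array per sample, and values are on the log2 scale. The labels do not say whether replicates were separate mice or pools, so p-values measure only the spread between these samples, and 3 arrays per group limit the precision.

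The arrays were not equally alike. Mutant replicate 2 correlated at 0.922 to 0.938 with the other 5 arrays, which correlated at 0.967 to 0.989 with each other, and the principal component that set it apart held 57.1% of the variance. Mutant replicate 1 was most like control replicate 1 (r = 0.987, across probe sets, which are not independent). Bright genes were lower and dim genes higher on part of the mutant arrays. Relative to the control mean, the brightest 10% of genes had a median of −0.41 in mutant replicate 2 and −0.19 in mutant replicate 3, against −0.00 in mutant replicate 1. In group 2 of 10 from the dim end these medians were 0.16, 0.09 and −0.00. Values of the long non-coding RNA Xist and of the Y-linked gene Eif2s3y divided the arrays across the groups. Control replicate 1 and mutant replicate 3 had Xist at 11.04 and 10.72 and Eif2s3y at 4.88 and 4.77, while the other 4 arrays had Eif2s3y at 7.31 to 7.85. On those 4 arrays Xist was at 8.07 and 6.57 in control replicates 2 and 3 and at 8.03 and 5.57 in mutant replicates 1 and 2. In the sex-linked list, kept as a sample check, 4 of 4 tested members had a lower mutant mean (median −0.35), and Kdm5d (−0.54 ± 0.76, SE), Xist (−0.45 ± 1.42) and Uty (−0.16 ± 0.56) differed by less than their errors.

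**Figure D1:**
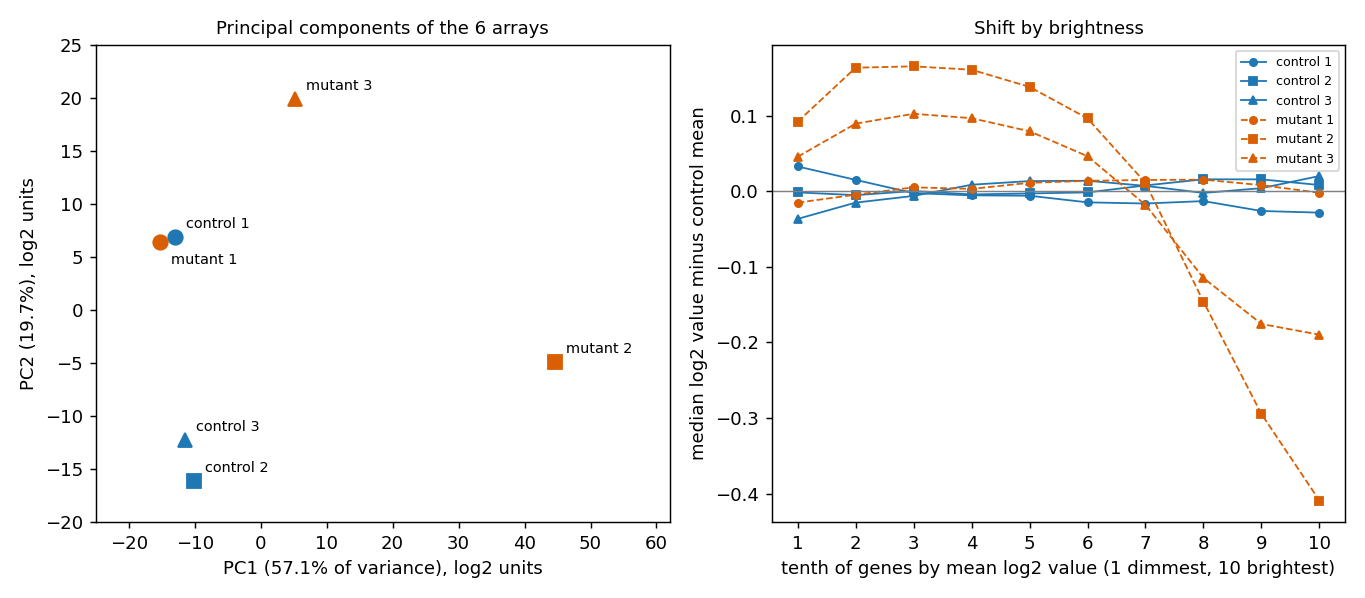
Left, the 6 arrays on the first principal components of the log2 values, which hold 57.1% and 19.7% of the variance; blue symbols are controls, orange symbols are mutants, and the symbol shape is the replicate number. Right, the median log2 value minus the control mean of genes in 10 equal groups from the dimmest to the brightest; mutant replicates 2 and 3 lie above 0 among dim genes and at −0.41 and −0.19 in the brightest group.

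No single gene differed between mutant and control progenitors past an adjusted p of 0.05. The genes with the lowest p whose values did not overlap leaned upwards in the chemokine gene Ccl2, the prolyl hydroxylase gene Egln3 and the cytokine signalling inhibitor gene Cish. They leaned downwards in Gas7, in the C-type lectin gene Clec4a3 and in Pld4, a gene of endolysosomal nucleic acid breakdown. Ccl2 was at 4.55 ± 0.09 in controls and 5.16 ± 0.07 in mutants (SD, n = 3 each), a difference of 0.61 ± 0.11 (SE). It was dim: its mean over all arrays, 4.85, was just above the cut for testing (4.84), and its control values were below that cut. Egln3 went from 5.07 ± 0.08 to 6.01 ± 0.41, Cish from 6.32 ± 0.16 to 7.08 ± 0.39, and the stefin gene Stfa1 from 5.05 ± 0.21 to 6.11 ± 0.61. The remaining higher genes of this kind were the microRNA gene Mir669g (1.21 ± 0.29, SE), the gamma-tubulin gene Tubg2 (0.62 ± 0.14), the kinase gene Dyrk3 (0.51 ± 0.13) and C1ql1 (0.65 ± 0.18). Lower ones were led by the microRNA gene Mir1898, at 6.30 ± 0.14 in controls and 4.82 ± 0.60 in mutants (SD). Gas7 stood at 7.60 ± 0.22 and 6.65 ± 0.28, Clec4a3 at 6.43 ± 0.26 and 5.26 ± 0.45, and Pld4 differed by −0.85 ± 0.18 (SE). Mitochondrial genes were also among them, the import subunit gene Timm17b (−0.86 ± 0.17, SE) and the ribosomal protein gene Mrpl27 (−0.60 ± 0.13), with Zfp780b (−0.71 ± 0.14) and Ppil1 (−0.58 ± 0.12). Each of these 16 genes had an adjusted p of 0.594 in limma.

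Over 13308 genes tested with limma, 0 passed the adjusted threshold, and 0 passed in the unmoderated test, in which 879 genes had an unadjusted p under 0.05. In limma 1068 genes had an unadjusted p under 0.05, 267 higher and 801 lower in mutants, where 665 would be expected by chance. The other splits of the 6 arrays into 3 and 3 gave 97 to 1243. The median log2 difference was −0.04 over the tested genes and 0.03 over all genes with a value. The excess of lower genes was therefore not separated from the filter on dim genes and the fall of bright genes on mutant replicates 2 and 3. The 3 mutant and 3 control values did not overlap for 15.4% of the tested genes, where chance gives 10%. Leaving out mutant replicate 1 gave 6 genes past the threshold and leaving out mutant replicate 2 gave 1. Array weights, estimated from each array's spread around its group mean, gave 2960, with the largest weight, 5.20, on mutant replicate 3. Estimated without the groups, the weight of that array was 0.66, below those of the controls and of mutant replicate 1. With 3 arrays per group the count of 2960 was treated as unreliable. Of 116 named genes, 62 had a difference that moved by over 1.5 times or took another sign on leaving out 1 array, 40 of them without mutant replicate 2.

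**Figure D2:**
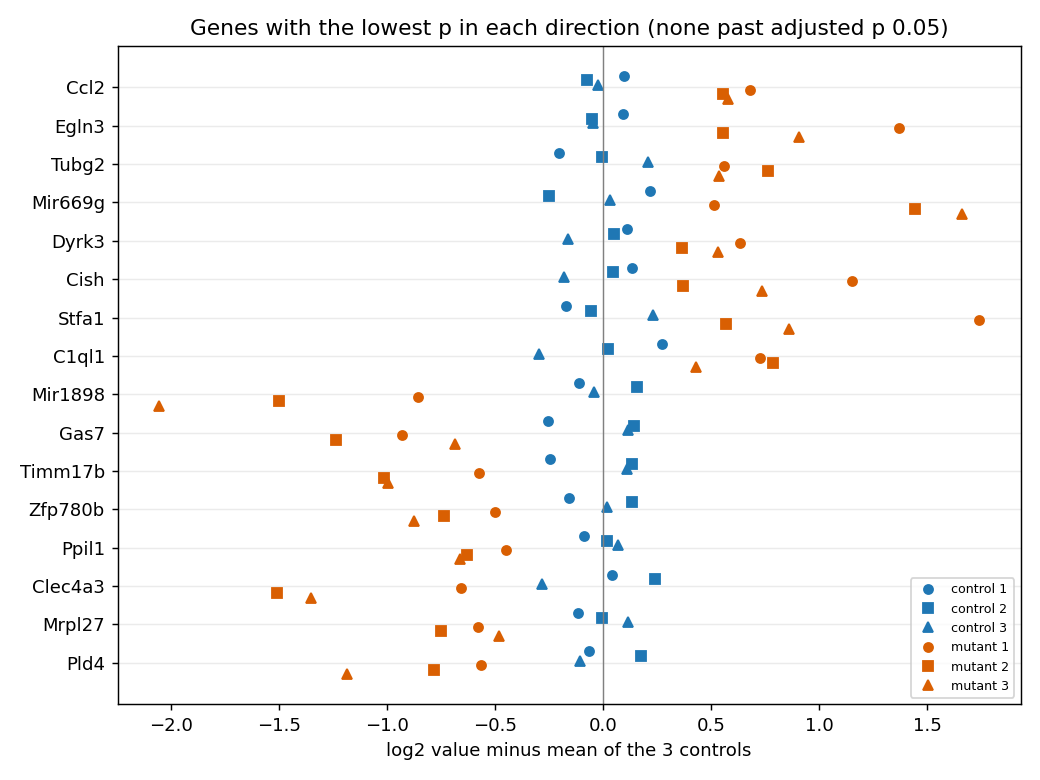
Log2 value minus the mean of the 3 controls (horizontal axis) for the 16 genes with the lowest p whose groups did not overlap; each symbol is 1 array, blue for control and orange for mutant, and the shape is the replicate number. None of these genes passed an adjusted p of 0.05; Ccl2 differed by 0.61 and Mir1898 by −1.47.

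Genes of cell division were lower as groups in mutant progenitors. In the S phase list, which holds genes of DNA replication, 22 of 23 tested members had a lower mutant mean, with a median log2 difference of −0.26. The replication fork gene Gins2 was at 9.08 ± 0.23 in controls and 8.32 ± 0.36 in mutants, the chromatin assembly gene Chaf1b at 7.02 ± 0.15 and 6.50 ± 0.16, and the helicase gene Mcm7 at 8.26 ± 0.13 and 7.87 ± 0.14 (SD, n = 3 each). In the list of G2 and M phase genes 23 of 23 members were lower, with a median of −0.20, among them the mitotic kinase gene Cdk1 (−0.54 ± 0.18, SE), Birc5 (−0.39 ± 0.14) and the centromere gene Cenpa (−0.50 ± 0.19, and −0.30 without mutant replicate 2). Both lists passed camera with its preset correlation (adjusted p = 4.95e-05 for S phase and 0.000216 for G2 and M phase), and neither passed with an estimated correlation (adjusted p = 0.652 for both). No member passed, either over all genes or adjusted over the list alone. The S phase score was −0.13, 0.03 and 0.11 in control replicates 1, 2 and 3 and −0.14, −0.30 and −0.35 in the mutants. The G2 and M phase score was −0.12, 0.08 and 0.03 against −0.11, −0.32 and −0.16. Control replicate 1 and mutant replicate 1 differed by less than 0.05 in both scores. With trends in brightness between arrays removed by cyclic loess, chosen after seeing the data, the medians became −0.10 for S phase, which still passed (adjusted p = 0.0494 in camera), and −0.01 for G2 and M phase, which did not (adjusted p = 0.624). With repeated quantile normalization they were −0.13 and −0.06, and again only S phase passed. Over all alternatives the adjusted p in camera or fry ran from 3.87e-08 to 0.652 for S phase and from 2.29e-07 to 0.652 for G2 and M phase.

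Genes of mitochondrial respiration and of the ribosome were also lower as groups. All 18 tested members of the oxidative phosphorylation list had a lower mutant mean (median −0.32), including the complex II gene Sdha (−0.36 ± 0.12, SE), the complex I gene Ndufa9 (−0.73 ± 0.28) and the ATP synthase gene Atp5b (−0.39 ± 0.15). Of 16 tested ribosomal protein genes 15 were lower (median −0.31), including Rpl8 (−0.62 ± 0.21), Rplp0 (−0.50 ± 0.20) and Rpl32 (−0.83 ± 0.37). Without mutant replicate 2 the differences of Ndufa9, Atp5b and Rpl32 were −0.37, −0.25 and −0.55. Without mutant replicate 1, where Rpl32 was at 11.93, Rpl32 was at −1.33 and passed in limma (adjusted p = 0.03; 0.00812 to 0.885 over all alternatives). The camera test gave adjusted p = 0.000372 and 0.00362, and with an estimated correlation adjusted p = 0.652 for both. By array, the oxidative phosphorylation score was −0.03, −0.62 and −0.21 in mutant replicates 1, 2 and 3, and the ribosomal score was 0.02, −0.53 and −0.32, while controls lay between −0.04 and 0.05. Without mutant replicate 2 neither list passed in camera (adjusted p = 0.0891 and 0.15; over the alternatives 1.34e-06 to 0.652 and 2.09e-05 to 0.652), with medians of −0.14 and −0.17. Without mutant replicate 1 the ribosomal median was −0.47. After cyclic loess the medians were −0.14 and −0.16, and the ribosomal list no longer passed.

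Lymphoid genes were lower as groups as well. In the early B lineage list 16 of 17 tested members had a lower mutant mean (median −0.27), among them the kinase gene Blk (7.54 ± 0.39 in controls and 6.79 ± 0.17 in mutants), Fcrla (7.87 ± 0.70 and 6.74 ± 0.50) and the repressor gene Bach2 (8.77 ± 0.40 and 8.06 ± 0.36; SD, n = 3 each). The exception was Ebf1, a transcription factor gene that starts the B cell programme, at 9.87 ± 0.11 and 9.92 ± 0.12. The B lineage factor gene Pax5 was at 8.55 ± 0.28 and 8.27 ± 0.46. In the lymphoid priming list 16 of 17 members were lower (median −0.25), including the Ikaros family genes Ikzf1 (−0.45 ± 0.13, SE) and Ikzf3 (−0.70 ± 0.22) and the chromatin organiser gene Satb1 (−0.48 ± 0.17). All 8 tested genes of V(D)J recombination, the joining of antigen receptor segments, were lower (median −0.27), including the end-joining genes Prkdc (−0.44 ± 0.16), Xrcc6 (−0.46 ± 0.18) and Nhej1 (−0.21 ± 0.11). Rag1, also listed under early B lineage and lymphoid priming, and Dclre1c were not tested because no probe set carried only their name. Camera gave adjusted p = 0.0014 for early B lineage, 0.00124 for lymphoid priming and 0.00362 for V(D)J recombination, and with an estimated correlation adjusted p = 0.652 for each of them. No member passed over all genes or adjusted over the list alone, and Rag2 is a member of all of these lists. Control replicate 1 had an early B lineage score of −0.31, within the range of the mutants (−0.41 to −0.19), against 0.19 and 0.09 in the other controls. Ly6d was at 7.18, 8.14 and 8.25 in control replicates 1, 2 and 3 and at 7.57 and 7.30 in mutant replicates 1 and 2, with its lowest value in mutant replicate 3. The mature B and plasma cell score was −0.14, 0.15 and 0.05 in these controls and −0.13, −0.44 and −0.33 in the mutants. Without mutant replicate 1 the early B lineage median was −0.30, no smaller than with it, and the adjusted p in camera was 0.0664 (2.46e-07 to 0.652 over all alternatives). Without control replicate 2 the median was −0.14, and the list still passed. After cyclic loess the medians were −0.08, −0.09 and −0.19 in the same order, and only V(D)J recombination still passed. With repeated quantile normalization they were −0.12, −0.10 and −0.21, and lymphoid priming did not pass. V(D)J recombination did not pass with array weights.

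**Figure D3:**
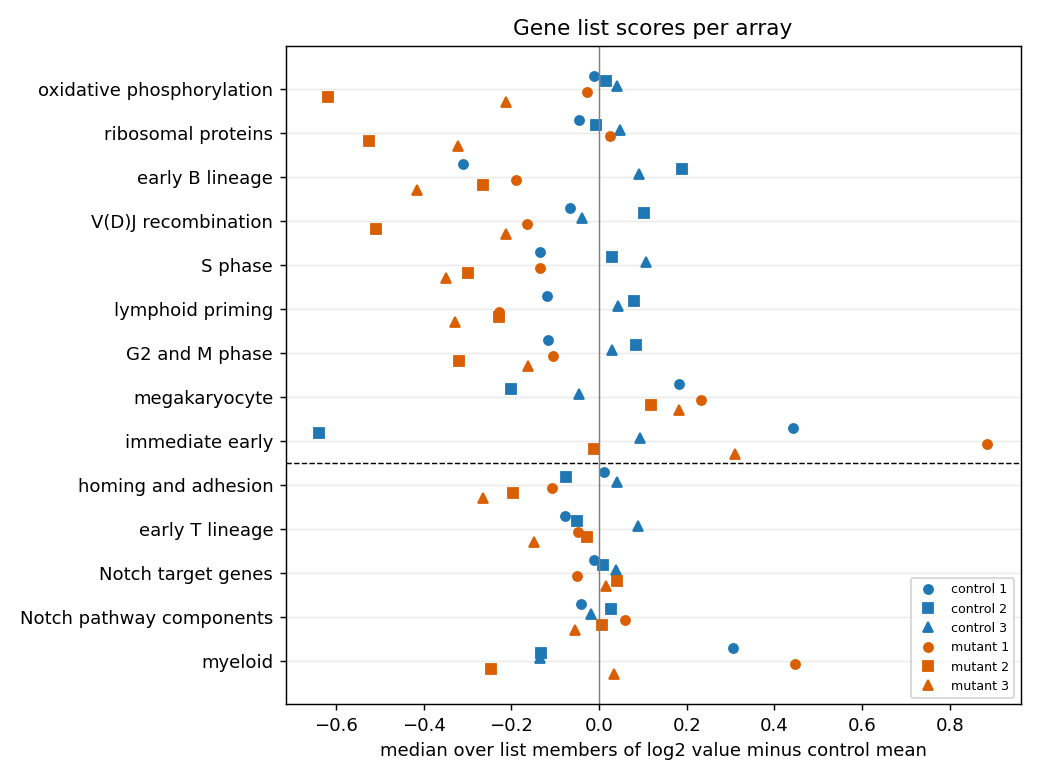
Median over the tested members of each list of the log2 value minus the control mean (horizontal axis), 1 symbol per array, blue for control and orange for mutant, with the shape giving the replicate number. Lists above the dashed line passed camera with its preset correlation and none with an estimated one; the oxidative phosphorylation score of mutant replicate 2 was −0.62 and that of mutant replicate 1 was −0.03.

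Notch and early T lineage genes did not pass as groups. Of 13 tested Notch target genes 7 had a higher and 6 a lower mutant mean; the median was 0.04, the mean was −0.02, and the median turned to −0.02 when arrays were centred on their medians (camera adjusted p = 0.564, direction up). On leaving out 1 array it ran from −0.03, without mutant replicate 3, to 0.07, without mutant replicate 1. Hes1 was at 6.72 ± 0.03 in controls and 6.88 ± 0.08 in mutants, Nrarp at 6.01 ± 0.06 and 5.82 ± 0.23, and Dtx1 at 6.04 ± 0.11 and 5.89 ± 0.13 (SD, n = 3 each). Notch1 (−0.15 ± 0.13, SE), Hey1 (0.25 ± 0.12), Notch3 (0.27 ± 0.14) and Heyl (−0.34 ± 0.21) did not pass either. Of 22 Notch pathway component genes 13 were lower (median −0.04, camera adjusted p = 0.692, direction up), including the protease gene Adam17 (−0.30 ± 0.15), with the glycosyltransferase gene Lfng at 0.19 ± 0.11 and Notch4 at 0.28 ± 0.16. Their median was −0.07 to −0.01 on leaving out 1 array. In the early T lineage list 10 of 19 members were lower (median −0.06, camera adjusted p = 0.99). Their median was −0.14 without mutant replicate 1 and −0.12 without control replicate 1, and it turned to 0.07 without control replicate 3. Cd7 differed by −0.62 ± 0.18, Cd5 by 0.28 ± 0.11 and Bcl11b, a T lineage commitment gene, by 0.23 ± 0.11, and Gata3 was at 5.67 ± 0.10 in controls and 5.70 ± 0.14 in mutants.

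Homing and adhesion genes, which progenitors use to leave the marrow and enter the thymus, leaned lower without passing. Of 17 tested members 13 had a lower mutant mean (median −0.19, camera adjusted p = 0.137), and the list passed without control replicate 2 (median −0.20, adjusted p = 0.0329; 0.0329 to 0.652 over all alternatives). The median was −0.04 after cyclic loess and −0.04 with repeated quantile normalization, and −0.09 without control replicate 1. The chemokine receptor gene Ccr2 was at 7.46 ± 0.07 in controls and 6.96 ± 0.26 in mutants, and the integrin genes Itga4 and Itga6 differed by −0.35 ± 0.16 and −0.33 ± 0.16 (SE). Ccr7 was at 6.91 ± 0.09 in controls and 6.91 ± 0.15 in mutants, and Selplg, the gene of the P-selectin ligand, at 9.11 ± 0.08 and 9.02 ± 0.35 (SD, n = 3 each). Ccr9 was too dim to be tested, at 4.70 ± 0.05 and 4.80 ± 0.05.

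Among the genes of the sort, Ly6d was at 7.86 ± 0.59 in controls and 7.29 ± 0.28 in mutants, Il7r at 10.11 ± 0.27 and 9.76 ± 0.04, and Kit at 7.15 ± 0.23 and 7.13 ± 0.17 (SD, n = 3 each). Thy1 (−0.21 ± 0.18, SE) did not pass, nor did Flt3 (−0.18 ± 0.20), which is not among the sort markers given in the labels. Bglap, the osteocalcin gene itself, was at 5.15 ± 0.10 and 5.28 ± 0.20, and Hbegf, whose primate form binds the toxin, at 5.50 ± 0.15 and 5.81 ± 0.06. In the list of IL-7 signalling genes 8 of 12 members were lower (median −0.12, camera adjusted p = 0.952), with Cish at the values given above and Mcl1 at −0.28 ± 0.19. The median was −0.03 without mutant replicate 2 and −0.21 without mutant replicate 1.

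Immediate early genes, which respond within minutes to stimulation and to cell handling, were higher as a group in mutants. Of 17 tested members 16 had a higher mutant mean (median 0.44), including Egr3 (5.75 ± 0.08 in controls and 6.10 ± 0.16 in mutants, SD, n = 3 each), Junb (0.44 ± 0.18, SE) and Egr2 (0.39 ± 0.18). The list passed camera (adjusted p = 4.95e-05) and not with an estimated correlation (adjusted p = 0.652). Its score was 0.44, −0.64 and 0.09 in control replicates 1, 2 and 3, and 0.88, −0.01 and 0.31 in the mutants, and without mutant replicate 1 the median was 0.20 and the call ended (adjusted p = 0.177 in camera; 1.58e-13 to 0.716 over all alternatives). Without control replicate 2 the median was 0.16, and the list still passed. Control replicate 1 and mutant replicate 1 also had the highest myeloid (0.31 and 0.45), erythroid (0.32 and 0.23) and stem and multipotent progenitor scores (0.10 and 0.22), against −0.25 to 0.03 on the other arrays. Without mutant replicate 1 Junb was at 0.27 and Egr2 at 0.25. The megakaryocyte list had 5 of 5 tested members higher (median 0.17), including Gp5 (0.21 ± 0.14), Itga2b (0.17 ± 0.14) and Treml1 (0.17 ± 0.16). It passed camera at adjusted p = 0.0358, had adjusted p = 0.652 with an estimated correlation, and ended without control replicate 2, control replicate 3, mutant replicate 1 or mutant replicate 3, with medians of 0.07, 0.17, 0.17 and 0.17 (highest adjusted p = 0.231 in camera; 0.00202 to 0.652 over all alternatives). It did not pass after cyclic loess (median 0.13), with repeated quantile normalization (0.14) or without a filter on dim genes.

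Apart from the megakaryocyte list, lists of other cell types did not pass in the test chosen beforehand, and some of them passed in alternatives, including ones with all 6 arrays and the deposited values. In the dendritic cell list 8 of 11 tested members were lower (median −0.15, camera adjusted p = 0.326), and the class II antigen presentation genes H2-Aa (6.72 ± 0.31 in controls and 5.67 ± 0.51 in mutants) and H2-Eb1 (5.86 ± 0.27 and 5.30 ± 0.08; SD, n = 3 each) fell in limma when adjusted over the list alone, a count of 2 members against 0 over all genes. The dendritic cell median was −0.03 without mutant replicate 2, −0.28 without mutant replicate 3, −0.25 without mutant replicate 1, −0.07 without control replicate 1 and −0.03 after cyclic loess. Mature B and plasma cell genes had 5 of 6 members lower (median −0.36, camera adjusted p = 0.0623), with Mzb1 at −1.02 ± 0.31 (SE), Cd37 at −0.48 ± 0.19 and Sdc1 at −0.59 ± 0.25, which was −0.28 without mutant replicate 2. That list passed in 7 of 23 alternatives: with the stricter filter on dim genes, with array weights, with the replicate block, with Y-linked expression as a block, with Xist as a covariate on the log2 or linear scale, and without control replicate 1 (median −0.49, adjusted p = 0.0206; 0.0206 to 0.652 over all). Without mutant replicate 2 its median was −0.22. Natural killer and innate lymphoid genes had 13 of 16 lower (median −0.09, camera adjusted p = 0.631), with Ccl5 at −1.03 ± 0.44, Klrd1 at −0.46 ± 0.25 and Xcl1 at −0.45 ± 0.33. Without mutant replicate 2 these were −0.56, −0.23 and −0.10. The list passed without control replicate 2 (median −0.29, adjusted p = 0.0276; 0.0276 to 0.96 over all), and the median turned to 0.04 without control replicate 1. Myeloid genes had 13 of 22 higher (median 0.02, turning to −0.04 when arrays were centred on their medians; camera adjusted p = 0.256), with Elane at 0.87 ± 0.53, Fcnb at 0.78 ± 0.54 and Csf1r at −0.37 ± 0.14. The myeloid list passed as higher in 6 of 23 alternatives. These were the stricter filter on dim genes, the replicate block, cyclic loess (median 0.16), the 4 arrays with high Y-linked expression (0.14), and leaving out control replicate 1 (0.17) or mutant replicate 2 (0.24, adjusted p = 0.000574; 0.000574 to 0.93 over all). Its median was −0.09 without mutant replicate 1 and −0.04 without control replicate 2. Erythroid genes had 6 of 11 higher (median 0.04, mean −0.03, camera adjusted p = 0.724), with Epor at 0.37 ± 0.13, Tfrc at −0.51 ± 0.24 and Slc4a1 at −0.41 ± 0.23. They passed on the 4 arrays with high Y-linked expression alone (median 0.24, adjusted p = 0.0325; 0.0325 to 0.976 over all), and on leaving out 1 array the median ran from −0.12, without mutant replicate 1, to 0.11, without control replicate 1. Stem and multipotent progenitor genes had 8 of 11 higher (median 0.09, camera adjusted p = 0.177), with Fgd5 at 0.18 ± 0.11, Hoxa9 at 0.16 ± 0.13 and Angpt1 at 0.23 ± 0.30. They passed in 2 of 23 alternatives, on those 4 arrays (median 0.13) and without control replicate 1 (median 0.11, adjusted p = 0.014; 0.014 to 0.854 over all). Without mutant replicate 1 the median was 0.01. Mature T cell genes had 7 of 9 lower (median −0.02, camera adjusted p = 0.99), with Cd3g at −0.56 ± 0.28, Cd28 at −0.27 ± 0.17 and Cd5, the member with the lowest p, at 0.28 ± 0.11. On leaving out 1 array the median ran from −0.09, without control replicate 1, to 0.06, without control replicate 3. Bone and stromal genes divided 4 to 4 (median 0.02, camera adjusted p = 0.6), with Sparc at −0.34 ± 0.16, Col3a1 at 0.25 ± 0.11 and Alpl at 0.14 ± 0.15, and a median of −0.04 to 0.05 on leaving out 1 array. Endothelial genes had 3 tested members (camera adjusted p = 0.952), of which Pecam1 was at −0.19 ± 0.15, and Cdh5 and Egfl7 differed by less than 0.05 with signs that turned with the normalization. Their median was −0.14 to 0.03 on leaving out 1 array.

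The remaining stress and pathway lists did not pass in the test chosen beforehand. Heat shock and unfolded protein response genes had 13 of 15 lower (median −0.18, camera adjusted p = 0.261), with Herpud1 at −0.53 ± 0.18 (SE), Hsph1 at −0.47 ± 0.27 and Hsp90b1 at −0.19 ± 0.12. This list passed without control replicate 2 (median −0.24, adjusted p = 0.00547; 0.00547 to 0.952 over all). Its median was −0.28 without mutant replicate 1 and −0.04 without control replicate 3, and it turned to 0.04 without mutant replicate 2. Genes of the p53 response had 6 of 8 lower (median −0.15, camera adjusted p = 0.256), with the cell cycle inhibitor gene Cdkn1a at 8.56 ± 0.21 in controls and 7.77 ± 0.54 in mutants (SD, n = 3 each), Mdm2 at −0.34 ± 0.18 and Ccng1 at −0.31 ± 0.21. The median was −0.22 without control replicate 1 and −0.09 without control replicate 2 or mutant replicate 3. Glycolysis genes had 11 of 14 lower (median −0.14, camera adjusted p = 0.6), with Tpi1 at −0.34 ± 0.14, Hk1 at 0.17 ± 0.14 and Pkm at −0.17 ± 0.11, which turned to 0.02 after cyclic loess. Without mutant replicate 2 the list's median was −0.02, and without mutant replicate 3 it was −0.08. Interferon response genes had 9 of 17 higher (median 0.04, mean −0.03, camera adjusted p = 0.826), with Usp18 at −0.26 ± 0.14, Trim30a at −0.30 ± 0.16 and Stat2 at −0.31 ± 0.17. On leaving out 1 array the median ran from −0.10, without mutant replicate 1, to 0.08, without control replicate 2. Glucocorticoid response genes had 5 of 9 higher (median 0.04, camera adjusted p = 0.657), with Tsc22d3 at −0.16 ± 0.14, Fkbp5 at 0.17 ± 0.16 and Zbtb16 at −0.20 ± 0.18. Their median was −0.09 without mutant replicate 1 and 0.10 without control replicate 1.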

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

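Cyclic loess and the fits by Y-linked expression or Xist were chosen after seeing the data; the other alternatives were not. The count of genes past an adjusted p of 0.05 in limma stayed at 0 without a filter on dim genes, with a stricter one, with other summaries, priors and normalizations, and with Y-linked expression as a block or Xist as a covariate. It was 2960 with array weights (genes higher in mutant, 815; genes lower in mutant, 2145), where mutant replicate 3 had a weight of 5.20 and mutant replicate 2 of 0.21. Leaving out 1 array gave 0 to 6 genes (0 to 4 higher, 0 to 2 lower), and an unadjusted threshold of 0.01 gave 144 (22 higher, 122 lower). The cause was not tested. The count of lists was 9; it was 0 with an estimated correlation and 0 with fry, which left the early B lineage median at −0.27 without a call, 5 after cyclic loess, where that median was −0.085, and 6 to 12 on leaving out 1 array. Across those the early B lineage median ran from −0.40 to −0.14 (−0.30 without mutant replicate 1, where the call was lost) and the homing median from −0.20 to −0.087 (past the threshold without control replicate 2, at −0.20). Of 641 list values under the alternatives, 36 lost a call, 19 gained one and 0 changed sign with a call in either fit. Medians of lists without a call did change sign, as for the early T lineage and myeloid lists. Of 116 named genes, 16 took another sign at least once.

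The replicate numbers did not pair the samples: deviations from the group means of equally numbered samples correlated at 0.13, 0.20 and −0.13. With the replicate block 0 genes and 11 lists passed, and not every sample correlated best with its own number. RMA values carry no signal over background, which limits what can be said of dim genes.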

Other observations

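The values in this paragraph and the next, and those of olfactory receptor genes below, were looked at after the data were seen. A group of microRNA genes of the Mir297, Mir466, Mir467 and Mir669 families had high values on the same pair of arrays. Of 24 such genes with a value, 22 lie within Sfmbt2 in a RefSeq table of GRCm38.p6, and for 20 of the 24 the 2 highest values were those of mutant replicates 2 and 3; the next most frequent of the 15 possible pairs of arrays led for 2 genes. Mir467e was at 9.02 and 8.66 on these arrays, against 6.67 in mutant replicate 1 and 6.66 ± 0.26 in controls (SD, n = 3). Mir669h was at 7.16 and 7.10, against 5.30 and 5.37 ± 0.16. Sfmbt2 itself was dim, at 4.29 and 3.98 against 3.94 ± 0.13 in controls. These microRNA sequences are close copies of one another, so probe sets can share signal. Some of the 24 were dim, such as Mir466b-3 (2.31 in controls), and dim genes as a whole were higher on mutant replicates 2 and 3. The share of all genes with that pair highest was not counted, so part of the 20 may follow brightness.

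Other genes also differed between the mutant arrays. Pla2g10os was at 8.23 and 7.28 in mutant replicates 2 and 3, at 3.04 in mutant replicate 1 and at 3.25 ± 0.50 in controls (SD, n = 3). The linker histone gene H1f2 was at 6.70 and 6.52 there, at 7.93 in mutant replicate 1 and at 7.98 ± 0.02 in controls. Stfa2l1, a stefin gene, was at 6.90 and 6.70 in mutant replicates 1 and 3 and at 4.93 in mutant replicate 2, against 5.09 ± 0.19 in controls. Of further genes of class II antigen presentation, H2-DMa was at 6.80 ± 0.07 in controls and 6.37 ± 0.25 in mutants, and the regulator Ciita was at 6.49 ± 0.07 and 6.31 ± 0.24. H2-Ab1, a dendritic cell list member that did not pass, was at 9.13 ± 0.28 and 8.83 ± 0.20.

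Tests of a weaker target, of other cell types and of the list-by-list parts below were chosen only after the results were seen, and those with cyclic loess, Y-linked expression and Xist after the data were seen; the estimated correlation was planned, but its use as a test of this explanation was not. For the 9 shifted lists, mutant replicate 2 alone was argued against as the source of the camera calls, since 7 of the 9 passed without it. This shows only that those 7 calls, at the preset correlation, did not need that array. Mutant replicate 3 stayed in that fit, and its brightest genes were low too (median −0.19). A trend shared by both arrays therefore stays open. The oxidative phosphorylation and ribosomal lists were the exceptions, with 0 of 2 passing without mutant replicate 2. Mutant replicate 3 was low in both as well, which keeps that part open. Its low scores were not separated from the fall of bright genes on that array. Sex was argued against only weakly, since all 9 passed in camera on the 4 arrays with high Y-linked expression alone. That fit left out control replicate 1, whose early B lineage score of −0.31 lay within the range of the mutants, and kept mutant replicate 2. Xist ran from 5.57 to 8.07 among its arrays, so these may not be alike in sex. All 9 also passed with Y-linked expression as a block, which decides little. Its low arrays were control replicate 1 and mutant replicate 3, so the balanced block could not change the differences. For samples pooled from both sexes, all 9 passed with Xist as a covariate on the log2 or linear scale (9 and 9). Mean Xist was 8.56 in controls and 8.11 in mutants, so these covariates had little to remove. A compressed intensity range could account for the G2 and M phase list. Its median went from −0.20 (quartiles −0.29 and −0.14) to −0.0103 (−0.11 and 0.05) after cyclic loess as the trend with brightness was removed. Such a range could not account for the immediate early list, which went from 0.44 to 0.51 and still passed. Early B lineage went from −0.27 to −0.08 and lymphoid priming from −0.25 to −0.09, and neither still passed. S phase went from −0.26 to −0.10, oxidative phosphorylation from −0.32 to −0.14 and ribosomal proteins from −0.31 to −0.16. V(D)J recombination moved less, from −0.27 to −0.19. Each lower list thus had a smaller median after cyclic loess, and a compressed range could account for part of each shift. Over all lists 4 of 9 passed, a count that decides nothing for the 9 together. Genes of a list moving together between arrays also remain open, as 0 lists passed with an estimated correlation. Of the 10 splits of the 6 arrays, 3 called at least 9 lists, among them the real split with 9 and another with 13. Splits other than the genotype thus called as many lists, and 10 splits are too few for a share under 0.05. For genes the real split gave 0, so a count over splits decides nothing. An effect of bone cell loss stays open and was not separated from these explanations.

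Mutant replicate 2 stood apart from the other arrays, and cells of another listed type stay open: 0 of 10 such lists had their highest score there by more than the SD of the other arrays, but bright genes were low on this array, which could hide markers. After cyclic loess 7 of the 10 scored below the highest other array by more than that SD, and the megakaryocyte, bone and stromal, and endothelial lists did not. The endothelial list then had its highest score in mutant replicate 2 (0.24, against 0.16 in control replicate 2). That gap of 0.08 was smaller than the SD of the other arrays (0.14). A weaker labelled target may account for it: the hybridisation controls, added in fixed amounts, were 0.233 above the highest other array, whose SD over 5 arrays was 0.0602. Olfactory receptor genes (1105 genes) had a median 0.16 above the control mean there, 0.08 in mutant replicate 3 and −0.02 in mutant replicate 1. An effect of the genotype on this sample was not tested.

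The lower early B lineage list may reflect uneven exclusion of Ly6D-positive cells by the sort, as a hypothesis. Over the 6 arrays the list's score without Ly6d rose with Ly6d (r = 0.978, exact permutation p = 0.00417; rho = 0.943, exact permutation p = 0.0167; 1 relation computed), and r was 0.977 without control replicates 2 and 3. Control replicate 1 had Ly6d at 7.18 and a score of −0.30, beside mutant replicate 2 at 7.30 and −0.26, so the relation did not follow the genotype alone. A change in B lineage transcription would give the same relation, and stays open as the biological explanation.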
